A study of Arabidopsis thaliana with 10 samples.

How the data were processed

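Messenger RNA was sequenced from 4-week-old Arabidopsis plants of 5 genotypes, per the labels: wild type Col-0, pnet2_ab, and 35S:NTL6-SRDX, 35S:NTL9-SRDX and 35S:NTL12-SRDX in pnet2_ab. The 10 libraries used here formed 5 groups of 2. The series text speaks of triplicates, whereas 2 libraries per genotype were analysed here. Libraries were grouped by their titles. The second NTL12 library carries NTL12 in its title and NTL2 in its genotype label, and it was kept in the NTL12 group.

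The deposited gene table gave raw counts per gene and library, and the authors also gave FPKM values for the same genes. HISAT2 2.0.4, HTSeq 0.6.1p1 and the TAIR10 genome are named in the submitters' processing notes. The strand setting of the counting and the handling of reads shared by overlapping or duplicated genes are not stated in the sources used here. Counts of such genes, close paralogs such as LTP3 and LTP4 among them, carry that uncertainty. The deposited counts were whole numbers, no table row lacked a gene, and the library sizes implied by FPKM lay at 0.905 to 1.106 of the count totals. Gene coordinates are those in the authors' table. Of 33602 genes, 32835 had a locus name in the reference table used for symbols, and 456 of 478 list members were found under their symbol.

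Libraries held 22.6 and 24.7 M counts in wild type, 28.3 and 23.0 in pnet2_ab, 24.1 and 25.3 in the NTL6 line, 23.6 and 25.5 in the NTL9 line, and 25.9 and 23.5 in the NTL12 line. A count of 0 allowed up to 3 counts at 95% confidence, or 0.106 to 0.133 CPM by library. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The 10 highest genes took 8.9% to 11.7% of the counts. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 6.0 to 9.49, and no pair was identical.

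Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low-count genes were removed with filterByExpr by group, which left 20334 genes. Scaling factors were computed by TMM and lay between 0.884 and 1.082. All 10 libraries were fitted together with 1 coefficient per group, and each comparison was tested with the quasi-likelihood F-test. P-values were adjusted over all tested genes of a comparison by the Benjamini-Hochberg method, with a threshold of 0.05. The biological coefficient of variation was 0.108 and the prior degrees of freedom 16.1. Standard errors of log2 fold changes were taken as the absolute value divided by the square root of F. Expression levels are CPM with TMM factors, given as mean ± SD over 2 libraries. Correlations and principal components used log2 CPM with a prior count of 2.

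The main comparisons were pnet2_ab against wild type and each line against pnet2_ab. Each line was also compared with wild type and with each other line. Genes were named by a fixed rule. In the main comparisons the rule took all tested PNET2 and NTL genes, and the 8 largest rises and 8 largest falls among genes past 0.05 that had a symbol, a mean of at least 5 CPM, and both libraries of a group beyond both of the other. It also took up to 4 members per list with the smallest adjusted p, and PR1, PR2, PR5, ICS1, PAD4, EDS1, SAG13 and PDF1.2a. In the other comparisons the 3 largest rises and falls were taken. The text prints a part of the genes the rule named, passing over most of those whose call or fold moved when a library was left out.

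The 28 gene lists covered the PNET2 family, the NTL family, the nuclear envelope, salicylic acid synthesis and metabolism, and salicylic acid response. Others covered pattern-triggered immunity, NLR receptors, camalexin, aliphatic glucosinolates, jasmonate, ethylene and jasmonate defence, senescence, the unfolded protein response, mitochondrial retrograde response, and photosynthesis. Further lists covered cell division, DNA damage, autophagy, abscisic acid, cold, heat shock, anthocyanin and the circadian clock. Markers of floral organs, roots, guard cells, epidermis and vasculature made up the last lists. Lists with at least 4 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with the correlation estimated from the data. The PNET2 family and the root markers had 3 tested members each. Counts of changed members are given with adjustment over all genes and over the list alone.

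Overlaps between comparisons that share pnet2_ab libraries were set beside 20 simulated data sets in which only shared noise linked them, and beside the number expected for independent lists. A further simulation of 20 data sets in each of 2 versions kept the mutant changes and moved each line's changes at random among genes of like pnet2_ab level. Its changes were as fitted or shrunk by their own standard errors. The reversal coefficient was the covariance of a pnet2_ab minus wild type difference with a line minus pnet2_ab difference, divided by the covariance of 2 pnet2_ab minus wild type differences that share no library. It was computed from log2 CPM over 4 assignments in which no library stood on both sides. It has no p-value, since genes are not replicates.

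Alternatives tried were RLE size factors, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 1 CPM in 2 libraries, fitting only the 2 groups compared, a block for the replicate number, limma on log2 FPKM with 1 or 0.1 added, a prior count of 0.5, and leaving out each library in turn. The replicate numbers did not pair the samples across groups, so no block was used. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

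The scripts were tested on simulated data before the real fit. For pnet2_ab against wild type, with 200 changed among 20002 simulated genes tested, edgeR recovered 44.8% of genes changed 1.5-fold, 80.6% changed 2-fold and 95.5% changed 4-fold, with 10 false among 157 calls. The reversal coefficient returned -0.536, -1 and -0.003 for true values of -0.5, -1 and 0 over 20334 genes. Camera called 0 of 10 unchanged lists, and a list made to rise had an adjusted p of 5e-37. The simulated genes varied independently, so this does not test false calls for lists whose genes vary together. Not analysed were splicing, sequence variants and transgene sequences, which the gene counts do not hold.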

Results

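Expression was compared between Arabidopsis wild type Col-0, the pnet2_ab mutant and 3 lines labelled as carrying 35S:NTL6-SRDX, 35S:NTL9-SRDX or 35S:NTL12-SRDX in pnet2_ab, with 2 libraries per genotype. PNET2 proteins lie in the inner nuclear membrane, NTL proteins are membrane-bound NAC transcription factors, and SRDX is a repression domain. LHCB1.3, encoding a light-harvesting protein, had the highest count in every library, at 1.97% to 2.54% of the total. Library totals were 22.6 to 28.3 M counts, and 20334 of 33602 genes were tested. Replicates correlated at 0.979 to 0.982 and libraries of different genotypes at 0.935 to 0.976. On the leading principal component, wild type scored -65.5 and -58.9 and pnet2_ab 59.5 and 62.2. The NTL9 line lay nearest wild type on this axis at -22.8 and -19.6, followed by the NTL6 line at -1.2 and -1.9 and the NTL12 line at 23.4 and 24.7. Groups, comparisons, gene lists and the rule for naming genes were chosen before the data were examined. Nothing in the labels says that replicates came from separate plants or cultures, so the p-values measure only the spread between these samples, which may be technical.

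**Figure D1:**
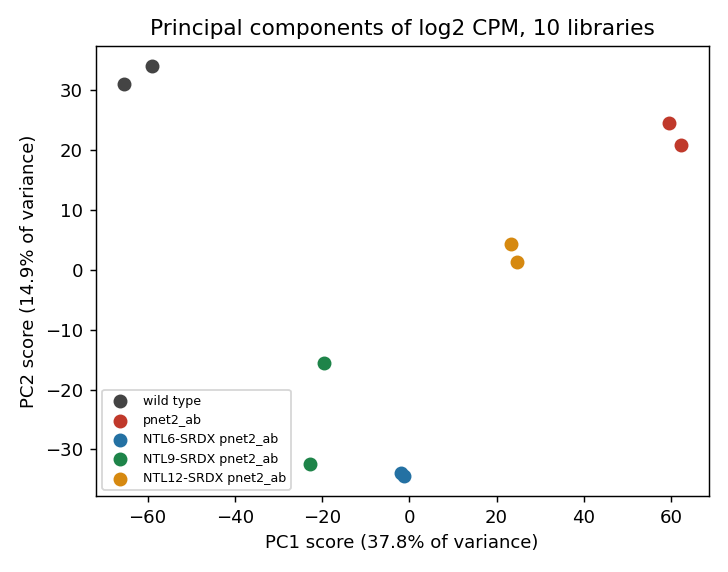
Scores of the 10 libraries on 2 principal components of log2 CPM, coloured by genotype, each point a library. Wild type and pnet2_ab lay at opposite ends of PC1 (37.8% of variance), with the 3 lines between them.

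The 3 tested PNET2 family genes differed in direction between pnet2_ab and wild type. AT1G28760 (chromosome 1, 10103158 to 10104588) had 5.75 and 3.75 CPM in wild type and 19 and 16.7 CPM in pnet2_ab, and rose by 1.92 ± 0.2 (log2 fold change ± SE, adjusted p = 9.1e-08, n = 2 per group). AT5G67610 (chromosome 5, 26960931 to 26963638) had 15.5 and 17.7 CPM in wild type and 9.3 and 8.07 CPM in pnet2_ab, and fell by 0.94 ± 0.17 (adjusted p = 0.00013). AT3G49840 (chromosome 3, 18484513 to 18487043) had 6.4 and 9.19 against 3.82 and 5.46 CPM, a change of -0.76 ± 0.26 with adjusted p = 0.027. That call was lost without the second wild-type library (-0.48, adjusted p = 0.28) and without the first pnet2_ab library (-0.52, adjusted p = 0.23). Over the 3 genes the median log2 fold change was -0.76 and the mean 0.07, opposite in sign. The labels do not say which of these genes are PNET2 A and B, and 1 of them rose in the mutant.

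None of the 17 tested NTL genes was higher past the threshold in any SRDX line than in pnet2_ab. NAC062, the gene named NTL6 (chromosome 3, 18362443 to 18364913), had 23.8 and 27.1 CPM in pnet2_ab and 18.1 and 19.7 CPM in the line labelled NTL6-SRDX, a change of -0.43 ± 0.13 with adjusted p = 0.025. That call was lost without the first NTL6 library (adjusted p = 0.17), the second NTL6 library (0.067) or the second pnet2_ab library (0.18). NTL9 (chromosome 4, 16888405 to 16890877) had 26.5 and 25.5 CPM in pnet2_ab and 27.7 and 22.9 CPM in the line labelled NTL9-SRDX (-0.04 ± 0.13, adjusted p = 0.87). The sources used here do not pair the name NTL12 with a locus, so the 2 genes given next are shown as NTL family members only. In the line labelled NTL12-SRDX, NAC014 (chromosome 1, 11975340 to 11978521) had 16.9 ± 0.935 CPM against 17.5 ± 1.64 CPM in pnet2_ab (mean ± SD, n = 2, log2 fold change -0.05, adjusted p = 0.91), and NAC062 had 36.5 and 29.5 CPM (0.38, adjusted p = 0.082). The transgenes were therefore not visible in gene counts, and each line is identified by its label alone.

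In pnet2_ab, the lipid transfer protein genes LTP3 and LTP2, 14 of 21 senescence, 24 of 31 pattern-triggered immunity and 11 of 14 cold-regulated genes rose against wild type, while all 50 tested photosynthesis genes fell. LTP3, a lipid transfer protein gene (chromosome 5, 23928971 to 23929745), rose by 7.17 ± 0.15 (adjusted p = 8.7e-19), from 0.888 ± 0.195 to 129 ± 7.58 CPM (mean ± SD, n = 2). LTP2 (chromosome 2, 16128378 to 16129158) rose by 5.16 ± 0.1, from 20 ± 1.52 to 715 ± 42.9 CPM. XTH19, a xyloglucan endotransglucosylase gene close to 0 in wild type (0.125 ± 0.177 CPM), reached 43.5 ± 3.31 CPM. LHCB4.3, a light-harvesting gene (chromosome 2, 16745653 to 16747400), fell by 2.5 ± 0.16, from 43.2 ± 2.2 to 7.68 ± 0.948 CPM. XTH31 fell by 1.94 ± 0.09, from 117 ± 6.08 to 30.6 ± 2.45 CPM, and MSRB6 fell by 2.39 ± 0.14. In all, 3494 genes rose and 3422 fell at an adjusted p under 0.05, and 1482 rose and 468 fell by at least 2-fold. The median over all tested genes was 0.035.

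All 50 tested photosynthesis genes fell in pnet2_ab, over all genes and when adjusted over the list alone (median -0.67, camera adjusted p = 2.5e-23, 0.27 with an estimated correlation). RBCS1A, a Rubisco small-subunit gene (chromosome 1, 25048158 to 25049424), fell by 0.96 ± 0.06, from 22500 ± 611 to 11600 ± 734 CPM, and RBCS3B fell by 1.27 ± 0.07. FBA1, a chloroplast aldolase gene, fell by 1.37 ± 0.08, and PSBS, needed for photoprotection, fell by 1.05 ± 0.07. Among 19 aliphatic glucosinolate genes 11 fell and 2 rose (11 and 3 over the list alone), with a median of -0.3 (camera adjusted p = 0.0048, 0.52 with an estimated correlation). UGT74C1 fell by 0.77 ± 0.09 and IMD1 fell by 0.66 ± 0.09. In the vasculature list 4 of 12 genes fell and none rose, also over the list alone, and SWEET11 fell by 0.43 ± 0.09. Its median was -0.22 and its camera adjusted p 0.037 (0.35 with an estimated correlation), a call lost without the first wild-type library (0.053) or the second pnet2_ab library (0.082).

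Senescence genes showed a median rise of 1.74, with 14 of 21 higher (16 over the list alone) and none lower (camera adjusted p = 6e-07, 0.051 with an estimated correlation). The senescence transcription factor genes ORS1 and NAP rose by 2.27 ± 0.21 and 1.74 ± 0.18. Of 31 pattern-triggered immunity genes 24 rose and none fell, also over the list alone (median 0.95, camera adjusted p = 4.5e-07, 0.22 with an estimated correlation). WRKY53 (chromosome 4, 12392370 to 12393982) rose by 3.22 ± 0.21 (adjusted p = 1.4e-10), WRKY33 by 1.33 ± 0.13 and BIR1 by 1.14 ± 0.11. In the salicylic acid synthesis and metabolism list 8 of 14 rose and none fell, also over the list alone. Its median was 0.98 and its camera adjusted p 0.0048 (0.31 with an estimated correlation), and CBP60G rose by 1.66 ± 0.17. The list mixes synthesis genes with regulators and genes that modify salicylic acid, so its shift does not show a change of synthesis. Its members ICS1, PBS3 and EPS1 had 12.6, 4.37 and 4.13 CPM in wild type and 13.9, 5.16 and 4.86 CPM in pnet2_ab. ICS1, PAD4 and EDS1 stood at 0.14 (adjusted p = 0.56), -0.13 (0.61) and 0.21 (0.36). The salicylic acid response list had 9 of 20 higher and none lower, also over the list alone, with AZI1 at 3.4 ± 0.21 and AED1 at 2.48 ± 0.23. Its median was 0.51 and its camera adjusted p 0.012 (0.47 with an estimated correlation), and 0.11 without the second pnet2_ab library. PR1, a salicylic acid marker (chromosome 2, 6241704 to 6242463), had 2.81 and 163 CPM in the pnet2_ab libraries, and its rise of 5.53 ± 1.01 became 0.66 (adjusted p = 0.39) without the second. It was 6.51 without the first of them and 6.27 without the second wild-type library.

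Cold-regulated genes also rose in pnet2_ab, 11 of 14 with none lower, also over the list alone (median 1.61, camera adjusted p = 4.9e-06, 0.26 with an estimated correlation). RD29A (chromosome 5, 21240849 to 21243613) rose by 1.69 ± 0.07, from 219 ± 14.9 to 710 ± 49.4 CPM, and ERD10 by 1.96 ± 0.07. In the abscisic acid list 6 of 12 rose and none fell, also over the list alone (median 0.58, camera adjusted p = 0.0042, 0.35 with an estimated correlation), with RD26 at 1.16 ± 0.14. Of 16 mitochondrial retrograde genes 11 rose and 2 fell, also over the list alone (median 1.26, camera adjusted p = 0.0013, 0.3 with an estimated correlation), OM66 by 1.93 ± 0.17. Of 12 DNA damage genes 7 rose and none fell, also over the list alone (median 0.96, camera adjusted p = 0.0031, 0.22 with an estimated correlation). GMI1, induced by double-strand breaks (chromosome 5, 8251378 to 8262154), rose by 2.56 ± 0.17, from 3.61 ± 0.575 to 21.3 ± 0.994 CPM, and the checkpoint gene RAD17 by 1.11 ± 0.2. In the list for ethylene and jasmonate defence 8 of 13 rose and none fell, also over the list alone (median 1.11, camera adjusted p = 0.0048, 0.3 with an estimated correlation), with ERF104 at 1.79 ± 0.2 and PDF1.2a at 0.32 (adjusted p = 0.6). The NTL family had 10 of 17 higher (11 over the list alone) and none lower (median 0.83, camera adjusted p = 0.00065, 0.25 with an estimated correlation), with NAC103 at 2.19 ± 0.31, NAC053 at 1.12 ± 0.19 and NAC014 at 0.88 ± 0.15. Of 8 floral organ genes 3 rose and none fell, also over the list alone (median 2.4, camera adjusted p = 0.01, 0.26 with an estimated correlation), and SEP3 rose by 2.9 ± 0.32, from 0.932 ± 0.309 to 6.91 ± 0.787 CPM.

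Autophagy genes rose in 8 of 14 cases with none lower, also over the list alone (median 0.37, camera adjusted p = 0.0075, 0.3 with an estimated correlation, and 0.051 without the second wild-type library), with ATG8A at 0.8 ± 0.13 and NBR1 at 0.69 ± 0.07. Immune receptor (NLR) genes rose in 9 of 23 cases with none lower, also over the list alone (median 0.27, camera adjusted p = 0.0075, 0.35 with an estimated correlation, and 0.13 without the second pnet2_ab library), ADR1 by 1.48 ± 0.2. Other lists were not shifted by camera. Of 13 camalexin genes 7 rose and 3 fell, also over the list alone, with GSTF6 at 2.93 ± 0.11 (camera adjusted p = 0.062, and 0.022 without the first pnet2_ab library). Of 22 jasmonate genes 10 rose and 5 fell, also over the list alone, with JAZ1 at 1.33 ± 0.17 and AOS at -1.02 ± 0.09 (camera adjusted p = 0.3). Of 19 unfolded protein response genes 4 rose and 7 fell (4 and 8 over the list alone), with BIP1 at -0.45 ± 0.07 (camera adjusted p = 0.34), and the median of -0.1 and mean of 0.06 differed in sign. Of 12 anthocyanin genes 2 rose and 4 fell (3 and 6 over the list alone), with CHS at 0.51 ± 0.1 and TT19 at -1.89 ± 0.31 (camera adjusted p = 0.4). In the cell division list 1 of 21 genes fell and none rose, also over the list alone (median -0.17). Its camera adjusted p was 0.062, and 0.011 without the first wild-type library, 0.0088 without the first pnet2_ab library and 0.049 without either NTL12 library. Of 21 nuclear envelope genes 4 rose and 1 fell (3 and 1 over the list alone), with NEAP2 at 1.04 ± 0.21 and SINE1 at -0.56 ± 0.14 (camera adjusted p = 0.11). Clock genes rose in 4 and fell in 2 of 15 cases (5 and 2 over the list alone, camera adjusted p = 0.4), with TOC1 at 0.43 ± 0.08. Heat shock genes rose in 3 of 12 cases (1 over the list alone, camera adjusted p = 0.95). Of 6 guard cell genes 2 rose and 1 fell, also over the list alone, with KAT1 at -1.06 ± 0.14 (camera adjusted p = 0.77). Epidermis genes fell in 3 of 5 cases, also over the list alone, with ATML1 at -0.42 ± 0.07 (camera adjusted p = 0.22). Of 3 root genes, too few for camera, NRT2.1 rose by 3.75 ± 0.52, PYK10 stood at 0.19 (adjusted p = 0.56), CASP1 at -5.1 ± 1.58 (adjusted p = 0.017, and 0.087, 0.068, 0.079 and 0.14 when any of the 4 libraries was left out), and the median of 0.19 and mean of -0.39 differed in sign. Of 26 lists, 16 were shifted with a preset correlation of 0.01 and 0 with estimated correlations.

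**Figure D2:**
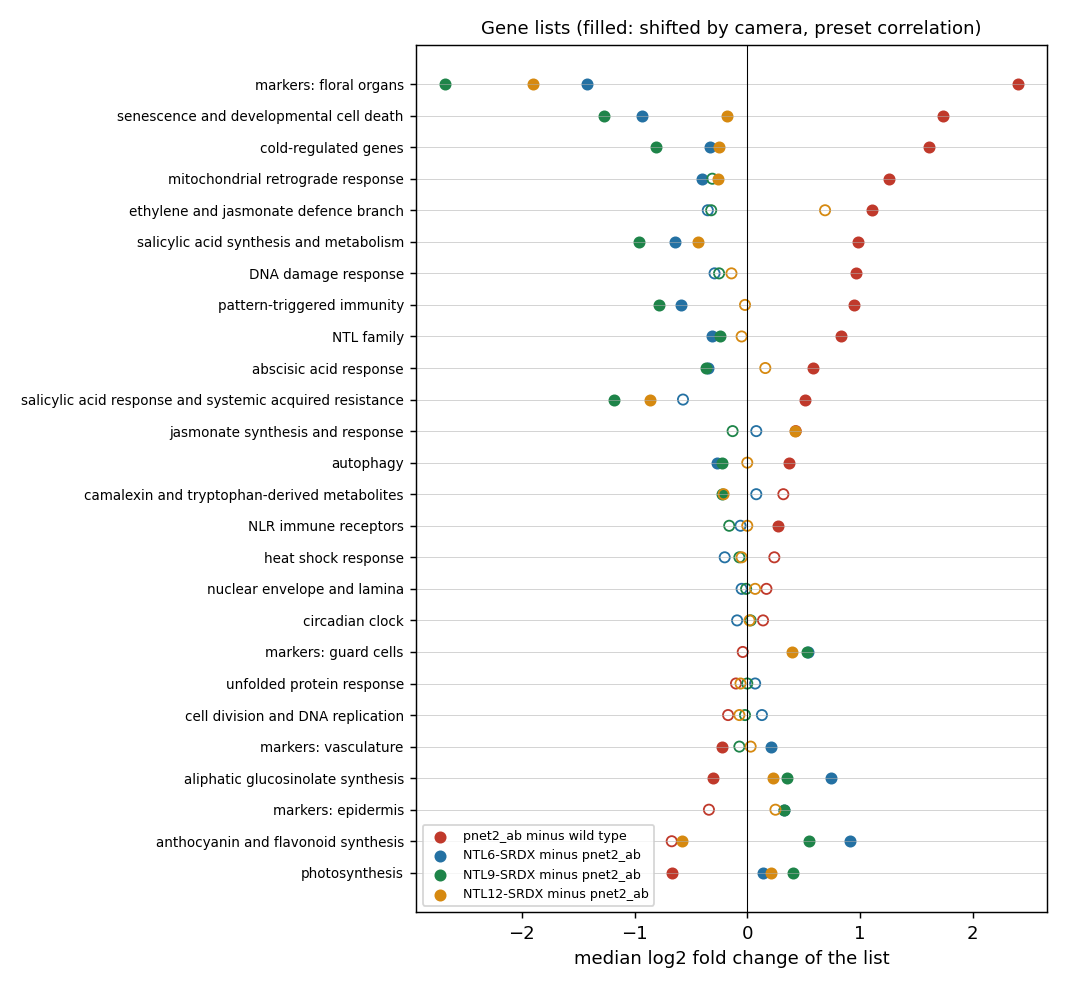
Median log2 fold change of each gene list in pnet2_ab minus wild type and in each line minus pnet2_ab, 1 point per comparison. Filled points mark lists shifted by camera with the preset correlation, as for senescence (1.74 in pnet2_ab, -1.27 in the NTL9 line).

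In the line labelled NTL6-SRDX, ASN1 and BT2 fell against pnet2_ab, glucosinolate genes rose in 18 of 19 cases and anthocyanin genes in 7 of 12. ASN1, an asparagine synthetase gene (chromosome 3, 17437884 to 17441243), fell by 4.31 ± 0.28 (adjusted p = 3.4e-10), from 23.9 ± 7.98 to 1.21 ± 0.0818 CPM. BT2 (chromosome 3, 17908192 to 17910525) fell by 3.63 ± 0.17, from 58 ± 4.05 to 4.68 ± 1.63 CPM, and XTH19 fell by 4.13 ± 0.24, from 43.5 ± 3.31 to 2.48 ± 0.141 CPM. LDOX, in anthocyanin synthesis (chromosome 4, 12004768 to 12006209), rose by 2.49 ± 0.27, from 2.47 ± 0.791 to 14.1 ± 1.52 CPM. PDF1.2a, a defensin marker of jasmonate and ethylene (chromosome 5, 17907069 to 17907598), rose by 4.27 ± 0.33, from 0.938 ± 0.403 to 17.9 ± 4.18 CPM. In this comparison 1780 genes rose and 1902 fell. Without the first NTL6 library these were 1183 and 1260, and without the second 1006 and 1177.

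Aliphatic glucosinolate genes rose in 18 of 19 cases in the NTL6 line, also over the list alone (median 0.74, camera adjusted p = 3.1e-13, 0.2 with an estimated correlation). IPMI2 rose by 1.04 ± 0.09, IMD1 by 1.03 ± 0.09 and CYP83A1 by 0.81 ± 0.07. Of 12 anthocyanin genes 7 rose and none fell, also over the list alone (median 0.91, camera adjusted p = 0.00013, 0.1 with an estimated correlation), TT19 by 2.16 ± 0.31 and DFR by 1.57 ± 0.3. Photosynthesis genes rose in 19 of 50 cases with none lower (21 over the list alone, median 0.14, camera adjusted p = 0.00013, 0.59 with an estimated correlation), RBCS1A by 0.43 ± 0.06. All 5 epidermis genes rose, also over the list alone (median 0.33, camera adjusted p = 0.0018, 0.2 with an estimated correlation), PDF2 by 0.51 ± 0.08. Senescence genes fell in 12 of 21 cases, also over the list alone (median -0.93, camera adjusted p = 1.3e-06, 0.055 with an estimated correlation), with SEN1 at -2.64 ± 0.22 and ORS1 at -1.74 ± 0.2. Of 31 pattern-triggered immunity genes 13 fell and 1 rose (16 and 1 over the list alone, median -0.59, camera adjusted p = 0.00013, 0.2 with an estimated correlation), with WRKY53 at -1.6 ± 0.18 and WRKY33 at -1.24 ± 0.13. Autophagy genes fell in 4 of 14 cases (5 over the list alone, median -0.27, camera adjusted p = 0.00084, 0.2 with an estimated correlation), with ATG8E at -0.92 ± 0.11. In the abscisic acid list 6 of 12 fell (7 over the list alone), with RD26 at -1.83 ± 0.14. Its camera adjusted p of 0.011 (0.53 with an estimated correlation) became 0.079 without the second pnet2_ab library. The salicylic acid synthesis and metabolism list was shifted, a call lost without the second pnet2_ab library. The salicylic acid response list was shifted only in fits with 1 library left out. CBP60G, AZI1 and AED1 had 9.37, 23.2 and 38.1 CPM in the NTL6 line against 24.3, 79 and 104 CPM in pnet2_ab. Members of these lists also went the other way, ACD6 and PR5 with 381 and 32.9 against 188 and 27 CPM. In all, 15 of 26 lists were shifted, 6 up and 9 down, and 0 with estimated correlations.

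In the line labelled NTL9-SRDX, photosynthesis genes rose in 47 of 50 cases against pnet2_ab, and LTP3 and 18 of 31 pattern-triggered immunity genes fell. LTP3 fell by 3.57 ± 0.11 (adjusted p = 1.1e-15), from 129 ± 7.58 to 10.9 ± 0.217 CPM. CRK13, a receptor kinase gene, fell by 4.29 ± 0.23, while XTH19 fell by 4.72 ± 0.25 and BT2 fell by 3.73 ± 0.17. LHCB4.3 rose by 1.85 ± 0.16, from 7.68 ± 0.948 to 27.6 ± 4.9 CPM, and OCT3 by 2.3 ± 0.27. AT5G67610, a PNET2 family gene, had 12 and 15 CPM against 9.3 and 8.07 CPM (0.63, adjusted p = 0.0081), a call lost without the second NTL9 library (0.46, adjusted p = 0.14) or the second pnet2_ab library (0.54, adjusted p = 0.075). In this comparison 2351 genes rose and 2188 fell.

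Photosynthesis genes rose in 47 of 50 cases in the NTL9 line (48 over the list alone, median 0.41, camera adjusted p = 1.8e-18, 0.25 with an estimated correlation). RBCS3B rose by 0.92 ± 0.07, from 4440 ± 358 to 8380 ± 824 CPM, and FBA1 by 0.97 ± 0.08. Of 19 glucosinolate genes 12 rose and none fell (14 over the list alone, median 0.35, camera adjusted p = 4.4e-05, 0.37 with an estimated correlation), UGT74C1 by 0.72 ± 0.09. Of 20 salicylic acid response genes 10 fell and none rose (13 over the list alone, median -1.18, camera adjusted p = 5.5e-05, 0.28 with an estimated correlation), with AED1 at -2.61 ± 0.23 and AZI1 at -2.38 ± 0.19. In the salicylic acid synthesis and metabolism list 7 of 14 genes fell (8 over the list alone), with CBP60G at -1.32 ± 0.17. That list had a median of -0.96 and a camera adjusted p of 0.00099 (0.25 with an estimated correlation). Of 31 pattern-triggered immunity genes 18 fell and none rose (19 over the list alone, median -0.78, camera adjusted p = 4.3e-07, 0.23 with an estimated correlation), with WRKY40 at -2.24 ± 0.28 and WRKY53 at -2.28 ± 0.19. Camalexin genes fell in 6 of 13 cases and rose in 2 (8 and 2 over the list alone, median -0.22, camera adjusted p = 0.0027, 0.23 with an estimated correlation), with GSTF6 at -2.41 ± 0.1. Senescence genes fell in 12 of 21 cases, also over the list alone (median -1.27, camera adjusted p = 3e-06, 0.066 with an estimated correlation), with ORE1 at -1.39 ± 0.19. Cold-regulated genes fell in 11 of 14 cases (12 over the list alone, median -0.81, camera adjusted p = 2e-05, 0.23 with an estimated correlation), with RD29A at -0.86 ± 0.07. Of 12 DNA damage genes 2 fell, also over the list alone, with GMI1 at -0.7 ± 0.15 (camera adjusted p = 0.23). Of 26 lists 15 were shifted, 5 up and 10 down, and 0 with estimated correlations.

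In the line labelled NTL12-SRDX, WRKY40, WRKY33 and 8 of 22 jasmonate genes rose against pnet2_ab, while 5 of 20 salicylic acid response genes fell. WRKY40 (chromosome 1, 30383691 to 30385499) rose by 2.13 ± 0.23 (adjusted p = 5.3e-06), from 6.17 ± 2.68 to 26.7 ± 0.118 CPM, and WRKY33 (chromosome 2, 16108361 to 16110766) by 1.21 ± 0.12, from 40.5 ± 8.6 to 93.8 ± 2.15 CPM. SZF1, a zinc finger gene, rose by 1.59 ± 0.13. Jasmonate genes rose in 8 of 22 cases and fell in 1 (11 and 2 over the list alone, median 0.42, camera adjusted p = 0.00057, 0.5 with an estimated correlation), with LOX4 at 1.61 ± 0.25, JAZ9 at 1.36 ± 0.17 and MYC2 at 0.96 ± 0.13. Of 50 photosynthesis genes 25 rose and none fell (33 over the list alone, median 0.21, camera adjusted p = 7.1e-11, 0.5 with an estimated correlation), RBCS2B by 0.48 ± 0.06. Glucosinolate genes rose in 6 of 19 cases (9 over the list alone, median 0.23, camera adjusted p = 0.00028, 0.5 with an estimated correlation), MAM3 by 0.99 ± 0.18. Of 20 salicylic acid response genes 5 fell and none rose (12 and 1 over the list alone). AED1 stood at -2.2 ± 0.22 and AZI1 at -1.66 ± 0.19. The falls of PR1, PR2 and PR5 in that list, -5.01, -2.22 and -0.99, became -0.14, -0.55 and -0.18 without the second pnet2_ab library. That list's median was -0.86 and its camera adjusted p 0.00057 (0.5 with an estimated correlation), and 0.087 without the second pnet2_ab library. Anthocyanin genes fell in 2 of 12 cases (4 over the list alone, median -0.58, camera adjusted p = 0.002, 0.34 with an estimated correlation), with CHS at -0.58 ± 0.1. Of 31 pattern-triggered immunity genes 4 rose and 5 fell (6 and 7 over the list alone, camera adjusted p = 0.86), with FRK1 at -2.97 ± 0.44. In all, 633 genes rose and 780 fell. The rises numbered 254 and 301 without the first and second NTL12 library and 352 without the first pnet2_ab library, and the falls 306, 329 and, without the second pnet2_ab library, 493. Of 26 lists 11 were shifted, 4 up and 7 down, and 0 with estimated correlations.

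**Figure D3:**
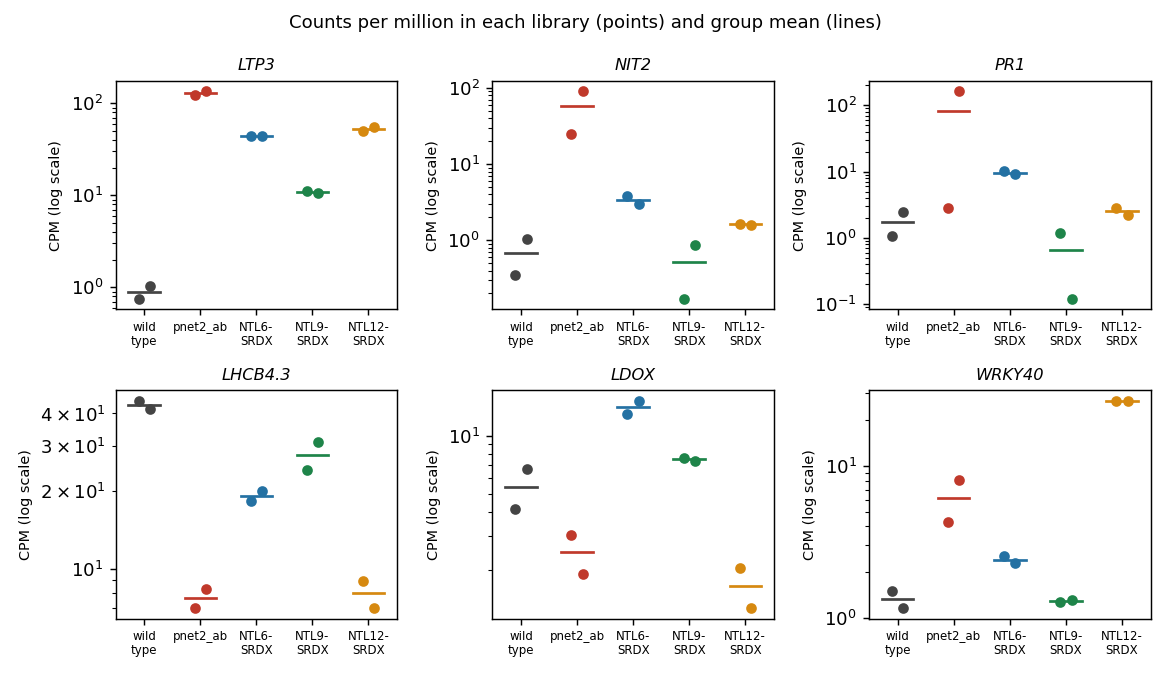
CPM on a log axis for 6 genes, with points for libraries and lines for group means. LTP3 had 0.888 CPM in wild type, 129 CPM in pnet2_ab and 10.9 CPM in the NTL9 line, and WRKY40 had its highest level, 26.7 CPM, in the NTL12 line.

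GMI1, ERD7 and 37 to 50 of 50 photosynthesis genes still differed from wild type in each of the 3 lines. Of 50 photosynthesis genes all 50 were lower in the NTL6 line (median -0.54), 37 in the NTL9 line (43 over the list alone, median -0.26) and 46 in the NTL12 line (47 over the list alone, median -0.39). The camera adjusted p was 1.6e-23, 1.8e-13 and 3.8e-16, and 0.3, 0.45 and 0.31 with an estimated correlation. GMI1 was higher by 1.98 ± 0.17, 1.86 ± 0.17 and 2.32 ± 0.17 in the NTL6, NTL9 and NTL12 lines. DNA damage genes were higher in 6, 6 and 7 of 12 cases, with medians of 0.89, 0.69 and 1.04 (camera adjusted p = 0.0029, 0.00041 and 0.0012, and 0.28, 0.28 and 0.16 with an estimated correlation). ERD7, a dehydration-induced gene, was higher by 2.45 ± 0.08, 2.11 ± 0.08 and 2.18 ± 0.08. LTP3 was higher by 5.61 ± 0.16 in the NTL6 line and 5.87 ± 0.16 in the NTL12 line. MAF5, an FLC-like floral repressor, was higher by 5.28 ± 0.52 and 5.03 ± 0.53 in the NTL6 and NTL9 lines. The mean level of LTP3 in the NTL9 line also lay above wild type. MAF5 had 15.6 CPM in the NTL12 line against 0.517 CPM in wild type. In the NTL12 line 17 of 31 pattern-triggered immunity genes were higher, also over the list alone (median 0.69, camera adjusted p = 1.7e-06, 0.16 with an estimated correlation), WRKY40 by 4.33 ± 0.28 and WRKY33 by 2.54 ± 0.13. In the NTL6 line 13 of 19 glucosinolate genes were higher (median 0.41, camera adjusted p = 3.8e-05, 0.42 with an estimated correlation), MAM3 by 1.58 ± 0.19. Against wild type 4787 genes changed in the NTL6 line, 2789 in the NTL9 line and 6205 in the NTL12 line, with 11, 9 and 16 of 26 lists shifted and 0 with estimated correlations. The count for the NTL6 line was 3189 without its first library. For the NTL9 line it was 1707 and 1670 without the first and second wild-type library and 1445 without the first NTL9 library, and 5 lists were shifted without the second NTL9 library.

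Genes that differed between pnet2_ab and wild type often moved back toward wild type in the lines. Among the 3494 genes higher in pnet2_ab, 1274 (36.5%) fell in the NTL6 line, 1673 (47.9%) in the NTL9 line and 568 (16.3%) in the NTL12 line. Among the 3422 lower genes, 1189 (34.7%), 1896 (55.4%) and 361 (10.5%) rose. Far fewer moved further from wild type, 52 higher and 58 lower in the NTL6 line, 36 and 18 in the NTL9 line, and 92 and 30 in the NTL12 line. Both sides of each comparison used the same pnet2_ab libraries, and noise in those libraries with no change in any line, which is chance with no effect, gave 0.4, 0.4 and 0.8 reversed genes among the higher and 0.1, 0.1 and 0.2 among the lower in simulation. Independent lists of these sizes would share 327, 376 and 134 higher and 300, 396 and 107 lower genes. The covariance between the mutant change and the line change was -0.51, -0.664 and -0.387, against -0.053, -0.055 and -0.054 in simulation. The 2 pnet2_ab libraries were not divided between the comparisons for these counts and covariances, since a share would hold 1 library, so part of the excess may come from shared libraries. For the NTL6 line 698 lower genes were reversed without its second library. For the NTL12 line 345 higher genes were reversed without the second pnet2_ab library and 245 and 272 without its first and second library. Its reversed lower genes numbered 197 without the first pnet2_ab library and 151 and 185 without its own libraries.

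A second simulation, added after these overlaps were seen, kept the sizes of each line's changes but moved them at random to other genes of like level. With the changes as fitted, noise included, it gave 613, 651 and 375 reversed genes among the higher and 690, 842 and 383 among the lower. It also called more genes than the data did, in the NTL12 line 1330 and 1582 against 633 and 780. With the changes shrunk to remove noise it gave 387, 436 and 215 among the higher and 446, 591 and 209 among the lower, and called 823 and 1131 genes in the NTL12 line. The 361 reversed lower genes of the NTL12 line lay within the range of the first version (354 to 428) and above that of the second (178 to 231), and the other 5 counts lay above both ranges. The covariance was -0.1, -0.105 and -0.085 with changes as fitted and -0.084, -0.091 and -0.08 with noise removed.

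The reversal coefficient, built so that no library stood on both sides, is -1 for a full return to wild type and 0 for none. It was -0.489 in the line labelled NTL6-SRDX (range -0.524 to -0.454 over 4 assignments of libraries), -0.657 in the line labelled NTL9-SRDX (-0.687 to -0.628) and -0.327 in the line labelled NTL12-SRDX (-0.362 to -0.291). Genes reversed in all 3 lines numbered 386 among the higher and 197 among the lower, against 15 and 40 with moved changes as fitted, 6 and 16 with noise removed, 0 and 0 with no change in any line, and 1 and 1 for independent lists. The 386 became 236 without the second pnet2_ab library and 194 and 206 without the first and second NTL12 library, and the 197 became 106 without the first pnet2_ab library and 99 and 111 without the NTL12 libraries. They rest on the same pnet2_ab libraries, and they included GSTF6, AZI1, AED1 and RD29A among the higher and RBCS3B and CYP83A1 among the lower. Their direction follows the line labels, since no transgene was seen.

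**Figure D4:**
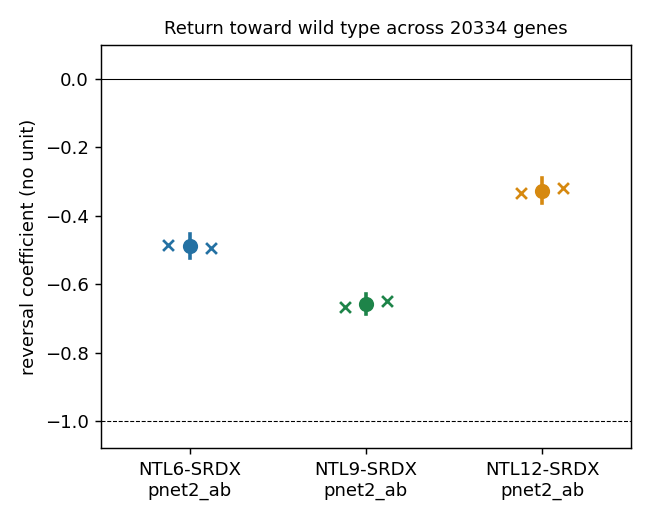
Reversal coefficient of each line across 20334 genes, without unit, where -1 is a full return to wild type. Large points are line means (-0.489, -0.657 and -0.327), bars the range over 4 assignments and crosses single libraries of the line.

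The lines also shared changes against pnet2_ab, but those counts rest on the same pnet2_ab libraries. In the NTL6 and NTL9 lines 1162 genes rose and 1283 fell together, among them BT2, XTH19 and CRK13 among the falls and LDOX and TBL26 among the rises. Simulation gave 0.2 and 0, independent lists 206 and 205, and the covariance was 0.463 against 0.055 in simulation. For the NTL6 and NTL12 lines 283 and 436 genes were shared, against 0.1 and 0.1 in simulation and 55 and 73 for independent lists (covariance 0.275 against 0.055). For the NTL9 and NTL12 lines 399 and 575 were shared, against 0.1 and 0.1 in simulation and 73 and 84 for independent lists (covariance 0.368 against 0.055). The correlation was 0.717, 0.551 and 0.655 for these pairs, against 0.493, 0.496 and 0.492 in simulation with no change in any line. For the NTL6 and NTL12 lines it lay little above that. Shared pnet2_ab noise alone sets that simulated value, so it is no reference for lines with changes of their own. With moved changes the correlation was 0.147, 0.165 and 0.162 as fitted, and 0.126, 0.154 and 0.141 with noise removed. Moved changes as fitted gave 566 and 437 for the NTL6 and NTL9 lines, 283 and 245 for the NTL6 and NTL12 lines and 327 and 269 for the NTL9 and NTL12 lines, and 348 and 266, 137 and 131, and 168 and 152 with noise removed. The 283 rises shared by the NTL6 and NTL12 lines lay within the range of moved changes as fitted (257 to 310). The total of 719 shared by the NTL6 and NTL12 lines was 351 and 383 without the first and second NTL12 library. The total of 974 for the NTL9 and NTL12 lines was 427 and 482 without those libraries and 645 without the second pnet2_ab library.

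Compared directly, the lines labelled NTL6-SRDX and NTL9-SRDX differed in FER1, NEET and NAS3, in 31 of 50 photosynthesis genes and in 12 of 19 glucosinolate genes. FER1, a ferritin gene (chromosome 5, 227953 to 230051), was lower by 2.5 ± 0.13 in the NTL6 line (adjusted p = 8.5e-11). There NEET was lower by 2.55 ± 0.24 and NAS3, a nicotianamine synthase gene, was lower by 1.71 ± 0.14. PDF1.2a was higher in the NTL6 line by 3.25 ± 0.31 and GSTF6 by 1.49 ± 0.1. Of 50 photosynthesis genes 31 were lower in the NTL6 line (42 over the list alone, median -0.28, camera adjusted p = 4.5e-18, 0.38 with an estimated correlation), with RCA at -0.46 ± 0.07. Of 19 glucosinolate genes 12 were higher (14 over the list alone, median 0.4, camera adjusted p = 6.9e-10, 0.38 with an estimated correlation), IPMI2 by 0.57 ± 0.09. In all 1232 genes differed, and 552 and 653 without the first and second NTL6 library and 482 without the second NTL9 library.

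Against the line labelled NTL12-SRDX, LDOX was higher and WRKY40 and WRKY33 lower in both other lines. In the NTL6 line 9 of 12 anthocyanin genes were higher than in the NTL12 line (10 over the list alone, median 1.64, camera adjusted p = 3.4e-08, 0.047 with an estimated correlation), LDOX by 3.07 ± 0.29, DFR by 2.6 ± 0.33 and CHS by 1.13 ± 0.1. In the NTL9 line 6 were higher, also over the list alone (median 1.16, camera adjusted p = 1.3e-05, 0.1 with an estimated correlation), LDOX by 2.17 ± 0.29. The log2 difference of WRKY40 was -3.46 ± 0.26 in the NTL6 line and -4.36 ± 0.28 in the NTL9 line, that of WRKY33 -2.45 ± 0.13 and -2.74 ± 0.14, that of BT2 -3.98 ± 0.17 and -4.08 ± 0.17, and that of SEN1 -2.91 ± 0.23 and -2.21 ± 0.21. For NAC062 it was -0.81 ± 0.13 in the NTL6 line and -0.92 ± 0.13 in the NTL9 line. Of 31 pattern-triggered immunity genes 11 were lower in the NTL6 line (14 lower and 2 higher over the list alone, median -0.27, camera adjusted p = 0.002, 0.49 with an estimated correlation) and 13 in the NTL9 line (16 over the list alone, median -0.55, camera adjusted p = 1.9e-07, 0.15 with an estimated correlation). In the NTL9 line 9 of 22 jasmonate genes were lower and 1 higher (11 and 2 over the list alone, median -0.66, camera adjusted p = 0.0013, 0.49 with an estimated correlation), with JAZ1 at -1.38 ± 0.16. In total 3549 genes differed between the NTL6 and NTL12 lines and 3311 between the NTL9 and NTL12 lines. The NTL6 to NTL12 count was 2298 and 2242 without the first and second NTL6 library and 2189 and 2218 without the NTL12 libraries. The NTL9 to NTL12 count was 2123 without the second NTL9 library and 2045 and 1975 without the NTL12 libraries.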

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

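The tests of flower tissue, depth and library exchange were chosen after the results were seen, and the test of shared noise was written before.

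The lines differed from each other in direct tests, which is why these results are listed here. Between the NTL6 and NTL9 lines 1232 genes differed, between the NTL6 and NTL12 lines 3549, and between the NTL9 and NTL12 lines 3311. The anthocyanin list shifted up against pnet2_ab in the NTL6 line (camera adjusted p = 0.00013, 0.1 with an estimated correlation) and the NTL9 line (0.026, 0.23 with an estimated correlation and 0.12 without its first library), and down in the NTL12 line (0.002, 0.34 with an estimated correlation). The direct difference had a camera adjusted p of 3.4e-08 between the NTL6 and NTL12 lines (0.047 with an estimated correlation) and of 1.3e-05 between the NTL9 and NTL12 lines (0.1 with an estimated correlation).

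The return of pnet2_ab changes toward wild type was weighed against shared noise and library scaling. Noise in pnet2_ab libraries used on both sides would give a coefficient near 0 when no library stands on both sides, and the value nearest to 0 over all lines and assignments was -0.291. The library scaling tests tried here were dropped, since a constant shift drops out of the centred coefficient and RLE size factors moved too little. A constant shift would add reversed genes in 1 direction and remove them in the other. In the NTL6 line 1274 higher and 1189 lower genes were reversed, against 327 and 300 for independent lists. The NTL9 line had 1673 and 1896 against 376 and 396. These counts argue against a constant shift as their source in those lines. The NTL12 line had 568 and 361 against 134 and 107, but its 361 lower genes lay within the range of moved changes as fitted. A constant shift therefore stays open for the counts of the NTL12 line. It is not the source of that line's coefficient of -0.327 (range -0.362 to -0.291), from which a constant shift drops out. Scaling also stays open for errors of scale that vary by gene. An effect of the genotype of the lines on pnet2_ab changes stays open as a hypothesis, found and tested on the same libraries, and growth conditions of single genotypes may also differ.

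Salicylic acid genes differed between the 2 pnet2_ab libraries, with PR1 at 2.81 and 163 CPM, and 10 of 34 tested salicylic acid genes over 2-fold apart (0, 0, 2 and 0 in the wild type, NTL6, NTL9 and NTL12 groups). Their median ratio between the 2 libraries of a group was 1.55 in pnet2_ab and 1.39 in the NTL9 line. It was 1.17, 1.12 and 1.19 in wild type, the NTL6 line and the NTL12 line. Depth would spread other genes of like count as much, yet the median CPM ratio of the salicylic acid genes was 1.55 and the highest in 1000 random sets of those other genes was 1.21. That depth test replaced earlier ones on PR1 and on the ratio of depths, which could not tell depth apart. An exchange with a library of another group does not go with the correlation of 0.979 between the pnet2_ab libraries, against at most 0.967 for the second with any other library. A difference in salicylic acid response between the plants sampled stays open as a hypothesis, and so does an unrecorded difference in handling.

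Of 8 floral organ genes 3 were higher in pnet2_ab than in wild type (camera adjusted p = 0.01, 0.26 with an estimated correlation), with SEP3 at 6.91 CPM. Flower tissue in the sampled plants would bring organ identity genes with it. AP3, PI and SEP2 had log2 changes of 2.42, 2.22 and 2.39 near the 2.9 of SEP3 (adjusted p = 0.087, 0.15 and 0.17). Their levels in pnet2_ab were 1.25, 0.893 and 0.742 CPM. Without the first pnet2_ab library they stood at 1.29, 1.67 and 2.01, with SEP3 at 2.78. Without the second they stood at 3.03, 2.6 and 2.68, with SEP3 at 3.01. For 2 of the 5, AG at -0.68 and SEP1 at 0.85 (adjusted p = 0.53 and 0.5), the change plus 2 SE lay below the rise of SEP3, so flower tissue could not be told from its absence. An earlier change toward flowering in pnet2_ab also stays open as a hypothesis, and the developmental stage of the plants at sampling was not tested.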

How the results depend on the processing

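The alternatives were planned before the data were examined, and no test in this part was chosen after the result was seen. The 3 reversal coefficients stayed negative throughout. Of the named genes of the main comparisons, 5372 values kept their call with 1 library left out, 271 lost it, 36 gained it and 1 reversed: PR1 in the NTL6 line against pnet2_ab, 1.79 (adjusted p = 0.023) without the second and -4.07 without the first pnet2_ab library, against -3.08 with both. Most fits with 1 library left out dropped a library of a group outside the comparison. Such fits left fold changes nearly as they were and changed few calls, so the numbers kept overstate how stable the calls are. Calls could still change through the spread that all groups share. Outside the main comparisons, PR1 differed by 3.89 between the NTL6 and NTL9 lines (adjusted p = 0.073). Without either pnet2_ab library it stayed at 3.89 but passed the threshold. Under other settings 4818 values kept their call, 215 lost and 47 gained it. Limma on log2 FPKM with 1 and with 0.1 added gave 285 and 262 genes higher and 504 and 350 lower in the NTL12 line than in pnet2_ab (633 and 780 with edgeR), and log2 FPKM gave that line a coefficient of -0.277. With estimated correlations camera shifted 0 lists in each of 7 comparisons (16, 15, 15, 11, 11, 9 and 16 with the preset one). The cause was not tested. A replicate block, whose pairs correlated between -0.038 and 0.032, gave 3372 higher and 3358 lower genes in pnet2_ab. Group spreads rest on 2 libraries, and a group left with 1 was assumed to vary like the others.

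With 1 library left out, genes higher and lower ranged over 2458 to 3381 and 2845 to 3520 in pnet2_ab against wild type, and against pnet2_ab over 1006 to 1784 and 1177 to 1977 in the NTL6 line, 1662 to 2418 and 1493 to 2242 in the NTL9 line, and 254 to 709 and 306 to 848 in the NTL12 line. Against wild type the lines ranged over 3189 to 4923, 1445 to 2958 and 4476 to 6314 genes. The NTL6 to NTL9, NTL6 to NTL12 and NTL9 to NTL12 differences ranged over 482 to 1412, 2189 to 3738 and 1975 to 3527, and genes changed the same way over 1637 to 2508, 351 to 813 and 427 to 1013. Reversed higher and lower genes ranged over 851 to 1301 and 698 to 1225 (NTL6), 1184 to 1643 and 1384 to 1860 (NTL9), and 245 to 608 and 151 to 417 (NTL12). Shifted lists ranged over 13 to 18 in pnet2_ab, 10 to 17, 13 to 18 and 8 to 11 in the lines against pnet2_ab, and 10 to 11, 5 to 10 and 14 to 16 against wild type. Coefficients ranged over -0.493 to -0.485, -0.666 to -0.649 and -0.333 to -0.32, and are undefined without a wild-type or pnet2_ab library. The lowest counts came with fewer libraries in the groups compared. In the simulated pnet2_ab against wild type, 44.8% of 1.5-fold changes were recovered, with 157 of 20002 genes called. In the real comparison 6916 of 20334 genes were called. The cut-off set by the adjustment depends on that share, so the recovered percentage does not carry over to the real comparison.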

Other observations

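The families and the flowering genes of the next paragraphs were tests chosen after the results were seen, and the tests of chromosome position were written before.

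Some gene families, of which WRKY and NAC overlap the fixed lists, were shifted in pnet2_ab against wild type by camera with the preset correlation, and none of those named here with an estimated one. Of 55 tested WRKY genes 29 rose and none fell (median 1.05, camera adjusted p = 1.1e-07, 0.17 with an estimated correlation), and 12 of the 55 belong to the fixed lists. WRKY48 rose by 4.73 ± 0.29 (adjusted p = 5.2e-11). Against pnet2_ab, 26 WRKY genes fell in the NTL6 line and 28 in the NTL9 line with none higher, while in the NTL12 line 2 rose and 10 fell. Of 77 NAC genes 31 rose and 1 fell (camera adjusted p = 1.4e-05, 0.31 with an estimated correlation), and 26 of the 77 belong to the fixed lists. Tubulin family genes fell in 14 of 19 cases and rose in 1 (camera adjusted p = 0.00063, 0.34 with an estimated correlation), with TUA6 at -0.46 ± 0.06 and the chloroplast division gene FTSZ2-2 at -0.84 ± 0.08. Histone genes fell in 12 of 32 cases and rose in 1 (camera adjusted p = 0.022, 0.49 with an estimated correlation), with HTA10 at -0.55 ± 0.09. Auxin-inducible genes fell in 19 of 46 cases and rose in 4 (camera adjusted p = 0.023, 0.34 with an estimated correlation), with SAUR68 at -1.07 ± 0.24. Of 188 tested transposable-element genes 32 rose and 6 fell, with a median of 0.23, and camera did not shift them.

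The flowering repressors FLC and MAF5 rose in pnet2_ab, by 2.2 and 3.05 (adjusted p = 0.00016 and 0.00029), while MAF1, AGL31, MAF3 and MAF4 stood at 0.16, 0.18, 0.08 and 1.26 (adjusted p = 0.28, 0.21, 0.76 and 0.072). Without the first and second pnet2_ab library MAF5 stood at 3.86 and 1.39 (adjusted p = 1.3e-09 and 0.012) and MAF4 at 1.79 and 0.45 (adjusted p = 0.013 and 0.62). FLC had 0.60 and 0.58 CPM in wild type, 1.92 and 3.59 CPM in pnet2_ab, 2.89 and 2.99 CPM in the NTL6 line, 5.69 and 4.6 CPM in the NTL9 line and 4.89 and 5.78 CPM in the NTL12 line. MAF5, its relative, had 0.5 and 0.535 CPM in wild type and 1.37 and 7.58 CPM in pnet2_ab. It had 20.3 and 20.3 CPM in the NTL6 line, 17.1 ± 4.26 CPM (mean ± SD, n = 2) in the NTL9 line and 13.7 and 17.5 CPM in the NTL12 line. Against pnet2_ab MAF5 was higher by 2.22, 1.98 and 1.84 in the NTL6, NTL9 and NTL12 lines (adjusted p = 0.00019, 0.00047 and 0.0037). Without the first pnet2_ab library these differences were 1.42, 1.17 and 1.04. SPL4, linked to the floral transition, rose in pnet2_ab by 1.29 (adjusted p = 9.8e-06), while the repressor SVP stood at -0.08 (adjusted p = 0.44). FD rose by 1.32 (adjusted p = 0.0084), and LFY by 5.55 (adjusted p = 0.0018) from 0.025 to 1.34 CPM. AGL20, AGL8, SPL5, CO and AGL24 did not pass the threshold, at -0.16, -0.22, 0.66, 1.4 and -0.36 (adjusted p = 0.25, 0.8, 0.27, 0.19 and 0.06). AP1 rose in pnet2_ab by 8.32 (adjusted p = 0.00079), to 2.35 and 0.856 CPM from no counts in wild type. It had 0.595 and 0.422 CPM in the NTL6 line (-1.66 against pnet2_ab, adjusted p = 0.21, and -0.75 without the first pnet2_ab library). The NTL9 and NTL12 lines had no AP1 counts (-8.32 against pnet2_ab in each, adjusted p = 0.00099 and 0.0035).

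PNET2 is a nuclear envelope protein, and chromosome ends and centromeres take set places in the nucleus, so genes higher in pnet2_ab were tested for position. Within 3 Mb of a centromere lay 1846 tested genes, of which 322 were higher, against 3171 of 18397 elsewhere (odds ratio 1.01, 95% interval 0.891 to 1.15, Fisher's exact test p = 0.82). Within 2 Mb of a chromosome end lay 4427, of which 765 were higher, against 2728 of 15816 elsewhere (odds ratio 1, 95% interval 0.916 to 1.1, Fisher's exact test p = 0.96). Each centromere was placed at the 1 Mb window with the most transposable-element genes on its chromosome. On chromosomes 2 and 4, with centres at 4.3 and 3.9 Mb, the centromere and end zones overlap. Genes are not independent replicates, so the intervals may be too narrow. Both intervals lie below 1.5, the bound set before, so the higher genes did not gather at either position as defined here.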
